A study of Mus musculus with 768 samples.

How the data were processed

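RNA of single mouse cells was profiled, 96 at each of 8 time points, in libraries sequenced with single-end reads of 50 bp to a stated average of 325000 reads per cell. The cells came from embryoid bodies formed 2 days before doxycycline. Per the labels, libraries were made in 2 batches, and which cells belonged to which batch is not given in the sources used here. The values are TPM, transcript abundances scaled to a fixed total per cell, as deposited by the authors in 1 table of 27723 genes. The columns sum to 1000000 within rounding, which fits TPM, and hold no whole reads. TPM keeps no depth, so the reads behind each value are unknown and only the number of genes above 0 was used as a measure of depth. The submitters' processing notes name bcl2fastq, Picard and the mm10 genome without versions. The aligner and the gene annotation are not given in the sources used here, although the column names carry the word rsem. TPM values of a cell are shares of its total, so a few abundant genes lower all others, and short transcripts such as small RNA genes can reach high TPM from few reads. SMART-Seq2 reads carry no molecular identifiers.

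Time points were taken from the labels. No column of another sample was present, and no 2 columns were identical. Cells with at least 2000 genes above 0 were kept, 368 in all, and 400 were left out. For each time point and gene the mean TPM over kept cells and the share of cells above 0 were computed. Fold changes are log2 of (mean + 1) ratios, a scale that understates the change of low genes. A gene passed the filter with a mean of at least 10 TPM in the higher of the 2 time points and detection in at least 25% of its cells. As each time point is 1 sample, no p-value, standard error or count of changed genes was made. Lists of genes were fixed before the data were examined. A list's median log2 fold change over passing members was set against 10000 random lists of the same size, matched on mean expression in 20 bins, and given as a percentile. Members were counted as higher or lower at 2-fold, as a measure of size. Medians are given only for lists with at least 3 passing members. Shares have exact 95% binomial intervals, and a share of 0 is given with the limit of 3 cells over the number of cells. Scores per cell are means of log2(TPM + 1) over a list, and the relation of 2 scores was set against 1000 random pairs of matched lists.

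Genes named were chosen by a rule written before the data were examined: the 3 factor genes; the 10 highest and 10 lowest at 48 h against 0 h after leaving out unnamed gene models; up to 4 members of each described list with the largest change at 48 h against 0 h; the 5 highest and 5 lowest at 6 h against 0 h; and 5 transient genes. The same rules were applied to 30 h against 6 h after the library sets had been seen. Genes that the text names outside these rules, among them Sod1, Gapdh, Pou5f1, Dcx, Gap43, Stmn2 at 6 h, Olig2 and Apoe at 12 h, were chosen after their values were seen. Each gene named by the rules at 48 h against 0 h and at 30 h against 6 h that passed the filter and was above 0 at both time points was carried through the alternatives, except genes whose results are not reported here. Symbols are written in capitals in the table. Of the list genes 298 matched by symbol and 4 through a synonym in RefSeq (GRCm38.p6), and 3 were not matched. GENCODE M21 gave transcript lengths and GC content, for 82.8% of the 10545 genes compared.

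Alternatives fixed beforehand were pseudocounts of 0.1 and 10, means rescaled to a median log2 ratio of 0, the median over cells, no filter on low values, all cells, cells with at least 4000 genes, odd-numbered or even-numbered cells, detection at 10 TPM, scores without the 3 highest genes, ranges from the 5th to the 95th percentile, and 5 G2 and M genes. Alternatives added after seeing the data were the comparisons within a library set, cells with at least 1000 genes, detection among the 1000 highest genes of a cell, means without the highest cell of each gene, and removal of the trend with GC content. Folds, filter and list percentiles were tested on simulated cells drawn from the detection rates and levels of the earlier time point, with 200 genes changed 4-fold. At the cell numbers of 30 h against 6 h the median log2 fold change of the raised genes was 1.91, and at those of 48 h against 0 h it was 1.71. Of 100 lists of unchanged genes, 3 and 2 lay outside the central 95% of random lists. Each gene was drawn independently and these lists were picked at random. The check therefore does not cover lists whose members vary together between cells, and the percentiles of such lists were not calibrated by it. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.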

Results

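Single-cell RNA profiles were made from mouse embryonic stem cells grown as embryoid bodies, in which doxycycline switches on a cassette of the 3 transcription factors Neurog2 (also called Ngn2), Isl1 and Lhx3. This factor combination is known to drive pluripotent cells towards spinal motor neurons. Cells were taken before doxycycline (0 h) and 6, 12, 18, 24, 30, 36 and 48 h after it was added at 3 µg/ml, sorted as viable single cells into 96 wells per time point, and profiled by full-length SMART-Seq2 RNA sequencing. The labels name no separate culture within a time point, so each time point is 1 sample. No test of significance was made, every spread is between cells of 1 sample, and differences are described by their size.

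The depth of the cells differed strongly between time points. Of the 96 cells at each time point, 37 (0 h), 53 (6 h), 52 (12 h), 56 (18 h), 55 (24 h), 57 (30 h), 44 (36 h) and 14 (48 h) had at least 2000 genes above 0 TPM and were kept. The median number of genes in the kept cells was 5304 at 0 h, 7484 at 6 h, 4269 at 12 h, 7348 at 18 h, 6676 at 24 h and 6481 at 30 h, but 2894 at 36 h and 2141 at 48 h. Many values of 0 are therefore missed transcripts: Hprt, a gene that all cells use, was above 0 in 7.14% of the kept 48 h cells and in 59.6% of the 30 h cells. Shares of cells below are given with exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. A share of 0 is instead given with the limit of 3 cells over the number of cells. This lies below the exact upper limit, for example 6.82% against 8.04% for 0 of 44 cells.

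By the levels of Sod1 and Gapdh the time points also fell into 2 library sets that did not follow time. Sod1, a superoxide dismutase gene, had a mean of 65262 ± 28258 TPM (SD, n = 37 cells) at 0 h, 53733 ± 28716 (n = 52) at 12 h, 19553 ± 11779 (n = 44) at 36 h and 20085 ± 9391 (n = 14) at 48 h, and of 518 to 807 TPM at 6, 18, 24 and 30 h. Gapdh, a glycolytic gene, went the other way, from 1748 to 3665 TPM at 0, 12, 36 and 48 h to between 5409 and 11474 TPM at 6, 18, 24 and 30 h. Over 10545 genes the means at 6, 18, 24 and 30 h correlated with a Spearman rho of 0.906 to 0.955, the means at 0 and 12 h with 0.772, and the means at 12 and 18 h with 0.654. The means at 36 and 48 h correlated with those at 0 and 12 h and with each other at 0.482 to 0.646, inside the range of pairs across the sets (0.410 to 0.654), so 36 and 48 h were placed by Sod1 and Gapdh and not by correlation. These correlations are across genes, which are not independent replicates. Because of the sets, 30 h against 6 h and 12 h against 0 h are given beside 48 h against 0 h, each within 1 set by Sod1. All kept cells at 36 and 48 h had cell numbers of 26 or higher, while those at 0 and 12 h began at 2 and 1. At 36 and 48 h 0 cells had at least 4000 genes, against 31 and 33 at 0 and 12 h. Whether 0, 12, 36 and 48 h share 1 set of libraries was therefore not settled. The 0, 12, 36 and 48 h time points are called Sod1-high below and the others Sod1-low.

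The factor genes were examined first, since they check the labels. Lhx3, a LIM homeodomain factor of motor neurons, was above 0 in 1 of 37 cells at 0 h (2.70%, interval 0.0684 to 14.2%) and in 37 of 53 cells at 6 h (69.8%, 55.7 to 81.7%). Its mean was 0.119 ± 0.725 TPM at 0 h and 140 ± 209 TPM at 12 h within the Sod1-high set, and 13.6 ± 20.1 TPM at 6 h and 21.9 ± 28.2 TPM at 30 h within the Sod1-low set. Isl1, its LIM homeodomain partner, was above 0 in 5.41% of cells at 0 h, 71.7% at 6 h and 64.9% at 30 h, with means of 3.33 ± 18.7, 12.4 ± 17.2 and 40.8 ± 83.7 TPM. Neurog2, the proneural factor, was detected less often: it was listed at 0 in all 37 cells at 0 h, which allows a share of up to 8.11%, and was above 0 in 22.6% of cells at 6 h (12.3 to 36.2%) and 26.3% at 30 h (15.5 to 39.7%). At 48 h Lhx3 was above 0 in 3 of 14 cells (21.4%) and Isl1 in 2 of 14, and Neurog2 was listed at 0 in all 14, which allows up to 21.4%. The log2 fold change of Isl1 at 48 h against 0 h, 4.30, rested on those 2 cells and turned to -3.12 in even-numbered cells. In the mm10 assembly (annotation GRCm38.p6) Lhx3 lies on chromosome 2 at 26200212 to 26208249, Isl1 on chromosome 13 at 116298270 to 116309688 and Neurog2 on chromosome 3 at 127632733 to 127635636. Reads of the cassette and of the cell's own genes share these symbols and were not told apart. The shares depend on the detection limit: with 10 TPM or more required, Lhx3 was detected in 35.8% of the 6 h cells.

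**Figure D1:**
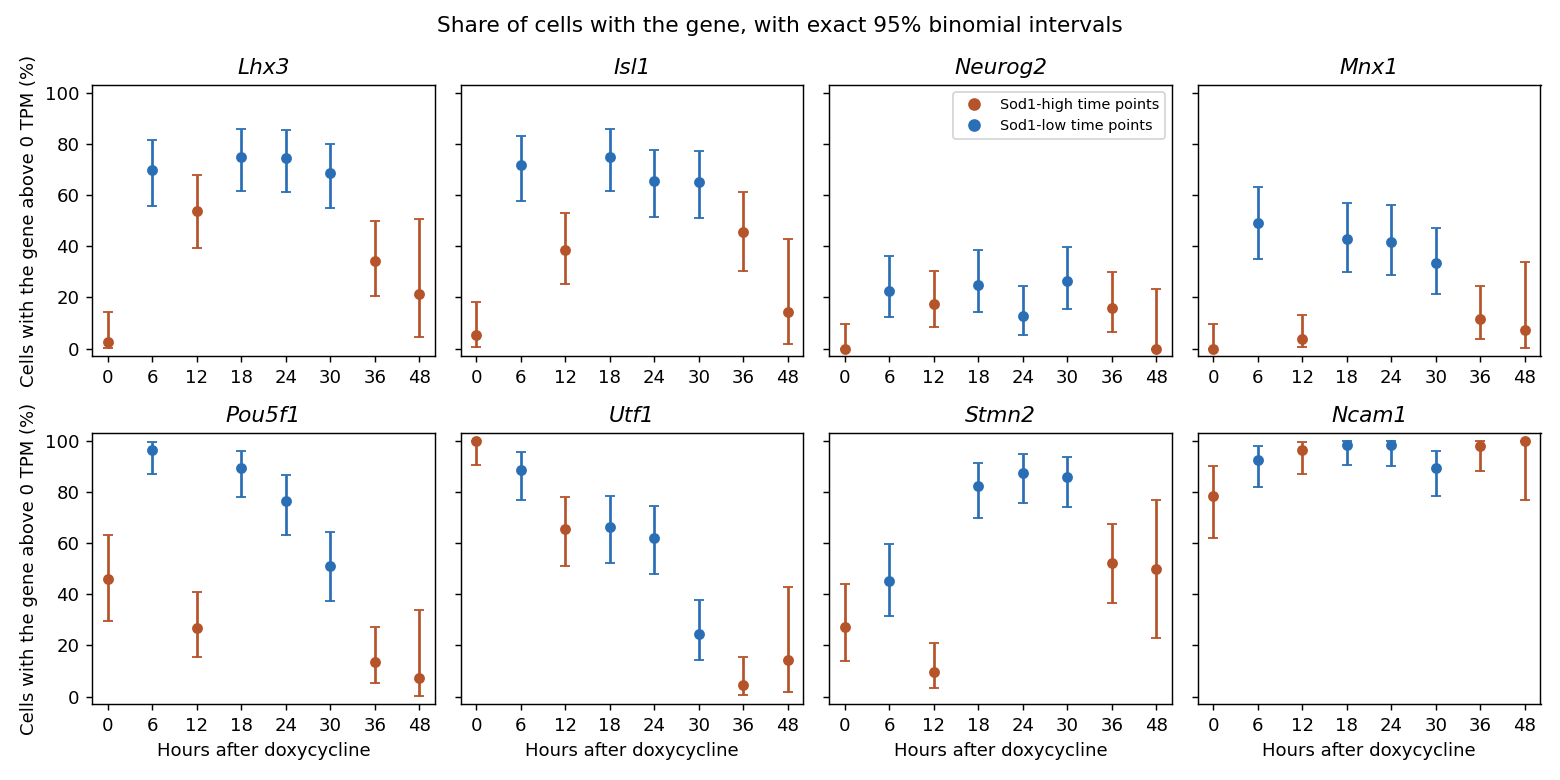
Share of kept cells with the gene above 0 TPM (y axis, percent) against hours after doxycycline (x axis, time points evenly spaced) for 8 genes, where points are shares, bars are exact 95% binomial intervals and colours give the 2 library sets. Within a set by Sod1, Lhx3 goes from 2.70% at 0 h to 53.8% at 12 h, and Utf1 from 88.7% at 6 h to 24.6% at 30 h.

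The core pluripotency list was lower at 48 h than at 0 h, at 30 h than at 6 h and at 12 h than at 0 h. At 48 h against 0 h the 12 core pluripotency genes that passed the filter had a median log2 fold change of -4.76, at percentile 0 of 10000 random lists matched on expression, whose median was -0.46. Of these genes 11 were at least 2-fold lower and 0 were at least 2-fold higher, and 4 were listed at 0 at 1 of the time points. Utf1, a chromatin factor of pluripotent cells, had 2434 ± 1414 TPM (n = 37) at 0 h and 9.07 ± 24.0 TPM (n = 14) at 48 h, a log2 fold change of -7.92. Dppa4 and Dppa5a, markers of pluripotent cells, had log2 fold changes of -6.27 and -3.32, and Tdgf1 (a Nodal co-receptor) and Fgf4 were listed at 0 in all 48 h cells against 107 and 99.4 TPM at 0 h. Within the Sod1-low set, 30 h against 6 h, the core list median was -1.35 (percentile 0), with 7 of 11 genes at least 2-fold lower and 0 higher. Pou5f1 (Oct4) had 307 ± 225 TPM (n = 53) at 6 h and 53.4 ± 101 TPM (n = 57) at 30 h and was above 0 in 96.2% and then 50.9% of cells. Dppa2 went from 107 to 8.14 TPM between these times, Utf1 from 63.8 to 7.29, L1td1 from 44.5 to 12.7 and Dppa5a from 2042 to 710. At 12 h against 0 h the core median was -0.99 at percentile 0.01. Between 0 h and 6 h, across the 2 sets, Pou5f1 went from 30.0 to 307 TPM and Utf1 from 2434 to 63.8, so levels of single genes at these times were not compared further. Several members departed from this. Sall4 had 1008 and 665 TPM and Nanog 1.61 and 2.57 TPM at 0 h and 48 h. Within the Sod1-high set Pou5f1 had 30.0, 31.9, 94.5 and 1.39 TPM at 0, 12, 36 and 48 h, and at 12 h against 0 h Lin28a was at 0.77 and Trim71 at 0.42.

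Naive pluripotency factors mostly failed the filter on level or share of cells. Of the 13 members, Zfp42 (Rex1) alone passed the filter at 48 h against 0 h, with 39.2 TPM at 0 h and a listed 0 in the 48 h cells. The mean log2 fold change over all 13 was -2.06 there. At 30 h against 6 h Zfp42 and Fbxo15 passed, at -0.50 and -2.26, and the mean over all 13 was -0.11. Formative and primed markers were divided. The median of these markers was -2.64 at 48 h against 0 h (percentile 6.68) and 0.77 at 30 h against 6 h (percentile 95.2), the latter turning to -1.06 with no cell left out. Dnmt3b, a DNA methyltransferase, had 463 TPM at 0 h and 30.7 at 48 h, whereas Otx2 had 65.4 TPM at 6 h and 141 at 30 h and Fgf5 31.1 and 56.1.

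Neuronal genes were higher late in the course. At 48 h against 0 h the 15 pan-neuronal genes that passed had a median log2 fold change of 4.67 (percentile 100), with 14 at least 2-fold higher and 0 lower. Elavl4 and Elavl3, neuronal RNA-binding proteins, had log2 fold changes of 7.19 and 6.24, Nefm (medium neurofilament) 6.71, Dcx (doublecortin) 6.48, Dpysl3 6.83 and Gap43, a growth cone protein, 6.03. These means rested on part of the cells: Elavl4 was above 0 in 42.9% and Gap43 in 57.1% of the 14 cells at 48 h. At 36 h, with 44 cells, the pan-neuronal median against 0 h was 4.83 (percentile 100), and at 12 h it was 1.46 (percentile 100), with 9 of 11 genes at least 2-fold higher. Within the Sod1-low set, 30 h against 6 h, the median was 1.47 (percentile 100), with 10 of 15 genes at least 2-fold higher and 0 lower. Stmn2, a microtubule regulator of growing axons, had 9.57 ± 20.5 TPM at 6 h and 124 ± 188 TPM at 30 h and was above 0 in 45.3% (31.6 to 59.6%) and 86.0% (74.2 to 93.7%) of cells. Nefl (light neurofilament) went from 8.02 to 72.2 TPM between these times, Elavl3 from 1.16 to 12.8 and Nefm from 3.29 to 21.9, while Tubb3 had 119 and 176 TPM, a log2 fold change of 0.56 that turned to -0.41 in even-numbered cells and to -1.69 with the median over cells. Taking the median over cells gave a pan-neuronal median log2 fold change of 0 in both comparisons, as most members were absent from over 50.0% of cells. With no cell left out, Elavl3 and Nefm turned to -1.51 and -0.057 at 30 h against 6 h.

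The axon guidance list was also higher at 48 h against 0 h and at 30 h against 6 h, and the Ebf and Onecut list at 48 h against 0 h. With the median over cells both lists had a median of 0 at 48 h against 0 h. The 3 Ebf and Onecut genes that passed at 48 h against 0 h, transcription factors of early neurons, had a median of 5.80 (percentile 99.99), with Ebf2 at 6.72, Ebf1 at 5.80 and Onecut2 at 5.30. Ebf2 went from 2.96 to 153 TPM between 0 h and 12 h and from 7.53 to 27.7 TPM between 6 h and 30 h, a log2 fold change of 1.75 that turned to -0.031 with no cell left out. It alone of its list passed at 30 h against 6 h. The other members lay between -0.42 (Onecut1) and 0.31 (Onecut2) there, and the mean over all 6 was 0.27. The axon guidance list had medians of 2.05 at 48 h against 0 h and 1.75 at 30 h against 6 h (percentiles 99.5 and 99.9). Robo2, a Slit receptor, had log2 fold changes of 3.85 and 2.25, and Nrp1, a semaphorin receptor, 4.47 and 1.60. The proneural cascade was mixed. Its median was 0.82 (percentile 89.5) and 0.84 (percentile 99.1), and at 30 h against 6 h 5 of 10 members were at least 2-fold higher and 2 lower. St18, a zinc finger factor, was higher at 2.20 and Srrm4, a neuronal splicing factor, at 1.68, whereas Gadd45g had a log2 fold change of -2.15. The list median at 48 h against 0 h was unstable, at -3.65 in odd-numbered cells, 3.37 in even-numbered cells and -1.68 in means without the highest cell of each gene. At 30 h against 6 h the list median turned to -0.39 with no cell left out.

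Motor neuron genes were detected at low levels. At 30 h against 6 h 3 of the 10 members passed, with a median of 1.18 (percentile 96.1). Lmo4 had 12.6 and 54.5 TPM, Slc18a3, the vesicular acetylcholine transporter, 3.96 and 10.2 TPM, and Mnx1 (Hb9), a motor neuron homeodomain factor, 5.93 ± 11.4 and 10.5 ± 27.4 TPM. Mnx1 was above 0 in 49.1% of cells at 6 h (35.1 to 63.2%) and 33.3% at 30 h (21.4 to 47.1%), and in 0 of 37 cells at 0 h, which allows up to 8.11%. Slc18a3 went from 0.0422 ± 0.257 TPM at 0 h to 84.5 ± 188 TPM at 12 h. Isl2 was above 0 in 1 cell each at 24, 36 and 48 h. The log2 fold changes of Lmo4 and Slc18a3 at 30 h against 6 h, 2.03 and 1.18, turned to -0.042 and -1.51 with no cell left out, and Slc18a3 to -0.77 with cells of at least 1000 genes.

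Progenitor genes gave a divided picture. Olig2, the factor of ventral spinal motor neuron progenitors, was listed at 0 in every kept cell at each of the 8 time points, and 0 of 57 cells at 30 h allows up to 5.26%. None of the 8 ventral spinal progenitor genes passed the filter at 48 h or at 30 h. Pax6, a neural progenitor factor, was listed at 0 in all 0 h cells and had 15.3 ± 40.0 TPM at 6 h and 41.2 ± 61.0 TPM at 30 h, above 0 in 37.7% and 73.7% of cells. Fabp7, a radial glia protein, went from 51.7 to 178 TPM and Vim from 94.5 to 244 TPM between 6 h and 30 h, and the 3 neural progenitor genes that passed had a median of 1.37 (percentile 99.3). At 48 h against 0 h 3 progenitor genes passed, with a median of 3.24 (percentile 99.6), Fabp7 at 6.18 and Sox9, a neural stem cell factor, at 3.24. Sox9 turned to -1.17 at 48 h against 0 h, and Fabp7 to -0.66 at 30 h against 6 h, with no cell left out. Sox1 was at or below 0.62 TPM at each time point.

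**Figure D2:**
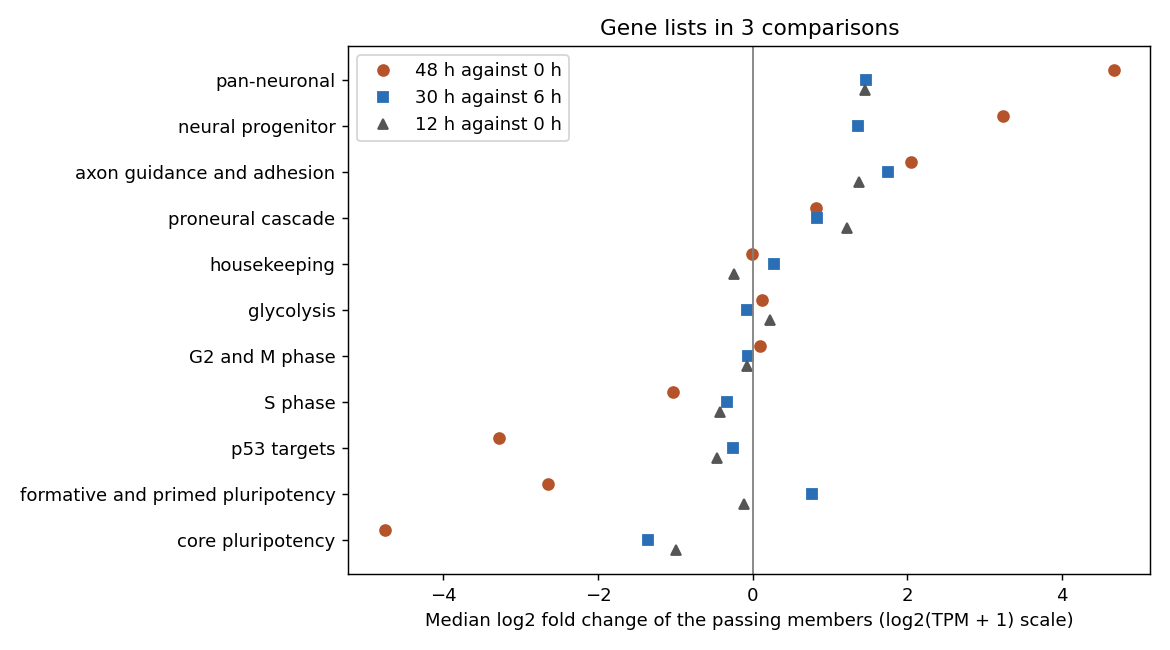
Median log2 fold change (x axis, log2(TPM + 1) scale) of the passing members of 11 gene lists (y axis) in 3 comparisons, 1 symbol per comparison. Core pluripotency lies at -4.76, -1.35 and -0.99 and pan-neuronal at 4.67, 1.47 and 1.46 for 48 h against 0 h, 30 h against 6 h and 12 h against 0 h; a missing symbol means fewer than 3 passing members.

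By the fixed rule of size, the genes with the highest log2 fold change at 48 h against 0 h were Crabp1, a retinoic acid binding protein (7.41), Tm2d2 (7.33), Smarca2, a chromatin remodelling ATPase (7.27), Elavl4, Dpysl3, Ebf2, Nefm, Nsdhl (6.59) and Krt18 (6.55), with 1 transcript known only by a sequence identifier. Among the 10 lowest were Hist1h2ap (-8.55), the small RNA genes Snord52, Snord87 and Mir715, and Rpl10l, Chchd10, Apoe and Med30, which were listed at 0 in all 48 h cells. Apoe was close to its 0 h level at 12 h, with 440 and 374 TPM, and Med30 had 371 and 461 TPM at 0 and 12 h but 0.776 to 4.90 TPM in the Sod1-low set. The median log2 fold change of all 5099 passing genes was -0.62, and changes at 48 h are to be read against that shift. On simulated cells at the numbers of this comparison, 39.8% of unchanged genes were 2-fold apart, so a single gene at 48 h carries little weight. Both simulated groups took the detection rates and levels of 0 h, with a median of 5304 genes per kept cell, against 2141 at 48 h. The lower depth at 48 h is thus not part of that share, which may be higher in the data.

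By the same rule within the Sod1-low set, a comparison added after the data were seen, the genes highest at 30 h against 6 h included T (Brachyury), a mesoderm factor, with a log2 fold change of 5.26, Nnat (4.54), the Wnt antagonist Frzb (4.44), Bace2 (4.41), the secretory granule protein Chga (4.25) and the neuropeptide gene Trh (3.82). The lowest included Spp1 (-4.01) and Fbp1, a gluconeogenic enzyme (-3.90). With no cell left out T turned to -0.12, and Cyp2e1, also among the 10 lowest at -3.74, to 2.10. On simulated cells of this comparison 5.40% of unchanged genes were 2-fold apart, and 95.0% of genes raised 4-fold were found at least 2-fold higher. The rules for 6 h against 0 h and for transient genes crossed the 2 sets. They named Snord33, Mtrnr2l and transcripts known only by sequence identifiers among the higher genes, and Med30, Wtap and Sod1 among the lower ones.

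Krt8 and Krt18, keratin genes of simple epithelia, had higher means at 12 h than at 0 h and at 30 h than at 6 h. Krt8 was above 0 in 35.1% of cells at 0 h (20.2 to 52.5%) and 69.2% at 12 h (54.9 to 81.3%), and its mean went from 4.48 ± 15.6 to 241 ± 406 TPM. Within the Sod1-low set its mean went from 206 ± 401 TPM at 6 h to 687 ± 633 TPM at 30 h, and Krt18 from 62.4 ± 107 to 297 ± 408 TPM. The epithelial adhesion gene Epcam had 164 TPM at 0 h and 9.34 at 48 h, a log2 fold change of -3.99, and Cdx2, a trophoblast factor, was listed at 0 in all kept cells. Tfap2c, a transcription factor of the same list, had 17.2 TPM at 0 h and was listed at 0 in all 48 h cells. Immediate early genes, which respond to stimulation and to cell dissociation, were higher at 30 h than at 6 h, with a median of 2.14 (percentile 99.99) over 4 passing genes, and of 0.57 with no filter on low values. Fos was at 2.77, Ier2 at 2.48, Egr1 at 1.80 and Junb at 1.22. At 48 h against 0 h the 2 passing genes were lower, Ier2 at -4.71 and Dusp1 at -2.20. Fos was not steadily higher, with 7.21, 10.5, 1.74 and 55.1 TPM at 6, 18, 24 and 30 h.

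Most markers of other cell types stayed low at 6 and 30 h. In the Sod1-high set, Pou4f1 of the sensory list passed the filter at 12 h against 0 h, at 2.60. The mean over all members at 36 h against 0 h was 1.26 for the glial and 1.12 for the mesoderm list. At 48 h against 0 h these means were -0.12 and -0.13. At 30 h against 6 h no member of the Hox, spinal interneuron, sensory and dorsal neuron, endoderm or two-cell-like lists passed the filter. Mbp of the glial list had 3.61 and 11.1 TPM, and Col1a2 of the fibroblast list 21.1 and 22.8 TPM. Col1a2 was at 1.32 at 48 h against 0 h (-0.21 with the median over cells). Rest, the repressor of neuronal genes, had 65.1 TPM at 0 h and 2.45 at 48 h, a log2 fold change of -4.26, and within the Sod1-low set 12.5 and 8.82 TPM at 6 and 30 h. Ptbp1, a splicing repressor of neuronal exons, had 59.3 TPM at 0 h and 4.79 at 48 h. Its log2 fold change of -3.38 turned to 1.01 with no cell left out and to 0.055 with cells of at least 1000 genes. Of the neuronal forms set against these repressors 2 passed at 48 h against 0 h and went apart, Ptbp2 at 1.60 (-0.60 with the median over cells) and Dpf1 at -3.66. Ptbp2 was at 1.71 at 30 h against 6 h and at -0.76 with no cell left out. The p53 target list had a median of -3.29 at 48 h against 0 h (percentile 2.90), with Sesn2 at -5.12 and Trp53inp1 at -3.85, the latter turning to 0.68 with no cell left out and to 0.65 with cells of at least 1000 genes, and of -0.26 at 30 h against 6 h (percentile 4.37). The unfolded protein list had a median of -0.39 at 30 h against 6 h, while its 2 passing genes at 48 h against 0 h were at least 2-fold higher. Of these, Asns was at 3.00 and turned to -3.16 with the median over cells, and the mean over all 8 members was -0.63. The cell cycle inhibitors had medians of 0.53 at 30 h against 6 h and -0.72 at 48 h against 0 h, with Cdkn1a at -2.29 and Gadd45a at -1.86, and the latter median turned to 1.34 with no cell left out and to 0.80 with no filter on low values. Glycolysis and housekeeping genes had medians of 0.12 and -0.0066 at 48 h against 0 h and of -0.074 and 0.28 at 30 h against 6 h. The medians at 48 h against 0 h were unstable over the alternatives, from -2.57 to 1.43 for glycolysis and from -1.19 to 0.61 for housekeeping.

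S phase genes had a median log2 fold change of -0.33 at 30 h against 6 h (percentile 0.72), -0.42 at 12 h against 0 h (percentile 1.26) and -1.03 at 48 h against 0 h (percentile 11.9), with Rrm2 (ribonucleotide reductase) at -2.94 and Gins2 (a replication factor) at -4.29 in the last. G2 and M phase genes had medians of -0.064, -0.067 and 0.094. The medians at 48 h against 0 h were unstable, at -4.02 (S) and -2.88 (G2 and M) in even-numbered cells and -0.24 and 1.02 in odd-numbered cells. Single genes were unstable at 48 h: Mki67, a proliferation marker, was at 3.41 against 0 h but at -3.32 in even-numbered cells, Aurkb, a mitotic kinase, at 3.04 but at -0.58 with no cell left out, and Gins2 at 1.77 in the latter. All 13 genes of each list were within 2-fold between 6 h and 30 h. At least 3 G2 and M genes were above 0 in 53 of 53 cells at 6 h, 56 of 57 at 30 h, 34 of 44 at 36 h (77.3%, 62.2 to 88.5%) and 11 of 14 at 48 h (78.6%, 49.2 to 95.3%). The fewer genes per cell at 36 and 48 h limit these last shares, and with 5 genes required the share at 48 h was 42.9%.

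The order of loss and gain was followed with mean log2 fold changes over all members of a list. Against 0 h in the Sod1-high set, the pan-neuronal list stood at 1.86 at 12 h, 3.59 at 36 h and 4.17 at 48 h, and the core pluripotency list at -1.23, -3.26 and -4.34. Against 6 h in the Sod1-low set, the pan-neuronal list stood at 0.58, 1.43 and 1.38 at 18, 24 and 30 h and the core list at -0.80, -0.95 and -1.20. With no cell left out the core values at 18 and 24 h were 0.010 and -0.10. Of the genes that moved at least 2-fold within that set, 5 of 9 core genes had covered 50% or more of their largest change at 18 h and the other 4 at 24 h, against 4 and 11 of 15 pan-neuronal genes. Over the alternatives the core counts were 3 to 6 at 18 h and 1 to 5 at 24 h, and the pan-neuronal counts 2 to 9 and 2 to 11, so an order of the lists was not fixed by them. The counts were also not corrected for GC content. Over genes, the ratio of 18 h to 6 h followed it with a Spearman rho of -0.312, and that of 24 h to 18 h with 0.394. Step sizes between successive time points, as the root mean square log2 difference per 6 h, were 2.04 (0 to 6 h), 2.04 (6 to 12 h), 1.91 (12 to 18 h), 0.76 (18 to 24 h), 0.50 (24 to 30 h), 2.13 (30 to 36 h) and 0.88 (36 to 48 h). The 4 steps of 1.91 or more cross the library sets. Over the 10545 genes, odd-numbered and even-numbered cells of the same time point differed by 1.64, 0.70, 1.73, 0.78, 0.74, 0.82, 2.36 and 3.27 at 0, 6, 12, 18, 24, 30, 36 and 48 h, while the steps over these genes, not divided by time, were 1.88, 1.89, 1.82, 0.78, 0.59, 2.03 and 2.49. Means over odd-numbered or even-numbered cells differed by 0.75 to 0.80 between 24 h and 30 h, where all kept cells gave 0.59. Within 24 h and within 30 h such means differed by 0.74 and 0.82. The step from 24 h to 30 h was therefore not told apart from the noise of these means. The step of 2.49 from 36 h to 48 h lay between the odd-even differences at these times, 2.36 and 3.27, which come from fewer cells per mean.

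Cells differed widely within a time point. The pluripotency score, the mean log2(TPM + 1) of 26 core and naive genes, was 3.22 ± 0.63 (SD, n = 37) at 0 h, 2.42 ± 0.59 (n = 53) at 6 h, 1.41 ± 0.60 (n = 57) at 30 h and 0.63 ± 0.32 (n = 14) at 48 h. The neuronal score, over 32 pan-neuronal and motor neuron genes, was 1.00 ± 0.36, 1.55 ± 0.69, 2.12 ± 1.07 and 2.25 ± 1.64 at these times. The 0 and 48 h cells are Sod1-high and the 6 and 30 h cells Sod1-low. These means are therefore not to be read as a single course. Of the 14 kept cells at 48 h, 0 had a pluripotency score inside the range of the 0 h cells, which allows up to 21.4%, and 8 had a neuronal score inside the 0 h range (57.1%, 28.9 to 82.3%). At 48 h 3 of the 14 cells lay within 0.25 of the upper end of that neuronal range. At 36 h the counts were 0 of 44 cells, which allows up to 6.82%, and 21 of 44 (47.7%, 32.5 to 63.3%). The first result depends on the cell filter, since with cells of at least 1000 genes 64.3% of the 48 h cells lay inside a wider 0 h range. Depth also bears on these counts. Kept cells had 3031 to 7044 genes at 0 h, 2056 to 3675 at 36 h and 2007 to 3104 at 48 h. The pluripotency score went with genes per cell, with r of 0.48 at 0 h and 0.47 at 48 h. Missed transcripts were therefore not separated from a lower score at 36 and 48 h. Within the Sod1-low set 56 of 57 cells at 30 h lay inside the pluripotency range of the 6 h cells and 52 of 57 inside their neuronal range. With ranges from the 5th to the 95th percentile these shares were 50.9% and 70.2%.

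**Figure D3:**
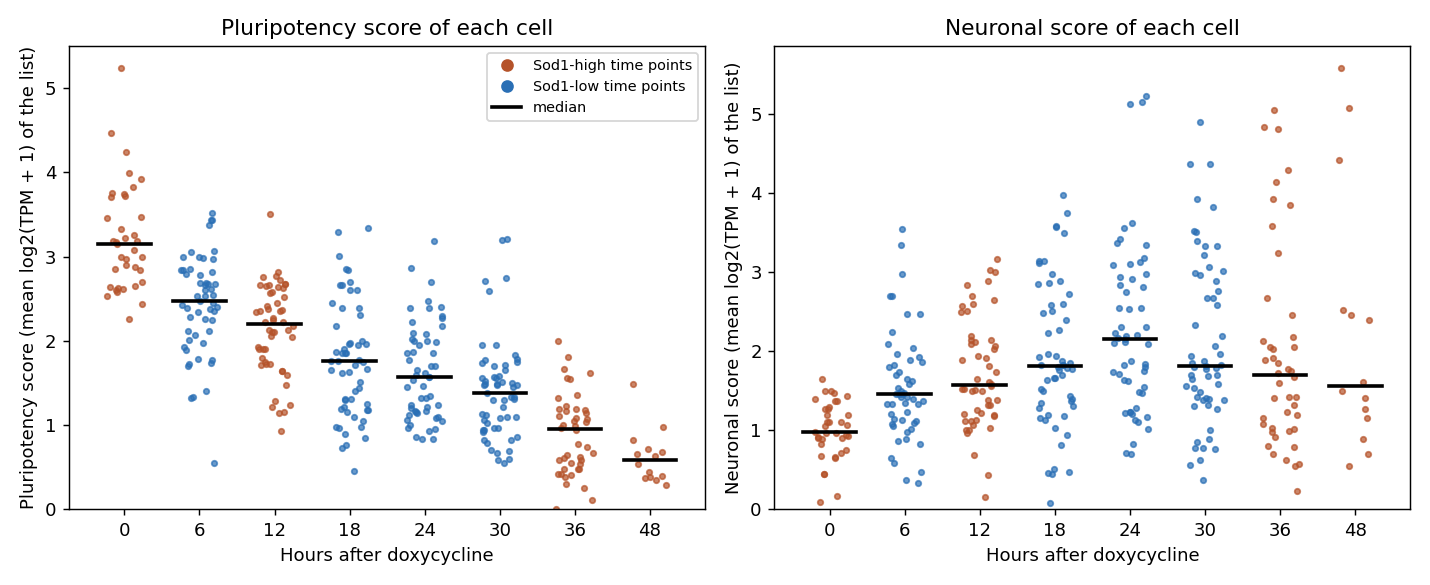
Pluripotency score (left y axis) and neuronal score (right y axis) of each kept cell, as mean log2(TPM + 1) of the list, against hours after doxycycline (x axis, time points evenly spaced), where points are cells, black lines are medians and colours give the 2 library sets. The mean pluripotency score is 3.22 at 0 h and 0.63 at 48 h, and the SD of the neuronal score goes from 0.36 to 1.64.

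Pou5f1 and Tubb3 (neuronal tubulin) were found together in 44 of 53 cells at 6 h (83.0%), 43 of 56 at 18 h (76.8%), 32 of 55 at 24 h (58.2%) and 17 of 57 at 30 h (29.8%, 18.4 to 43.4%). The shares that independent detection of the genes would give were 81.7%, 73.3%, 59.7% and 30.3%. Pou5f1 and Mnx1 were found together in 49.1% of cells at 6 h and 15.8% at 30 h. In the shallower Sod1-high set 3 of 37 cells at 0 h and 0 of 44 at 36 h had both Pou5f1 and Tubb3.

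Within a time point, cells with more neuronal expression had less pluripotency expression at 24 h and 30 h. The Pearson r of the scores was -0.52 at 24 h (Spearman rho -0.54, n = 55 cells) and -0.34 at 30 h (rho -0.34, n = 57), and without the 2 cells farthest from the median pluripotency score it was -0.48 and -0.33. At 6 h and 18 h r was -0.014 and -0.067, but -0.353 and -0.497 with cells of at least 4000 genes. With no cell left out it was 0.665 and 0.452 at these 2 times. A later start of the relation was therefore not fixed by these values. Random pairs of expression-matched lists had median r of 0.73, 0.73, 0.46 and 0.59 at 6, 18, 24 and 30 h, and the observed r lay at percentile 0 of 1000 pairs at each of these times. Given the number of genes per cell, the partial r was -0.39, -0.37, -0.53 and -0.45. In the Sod1-high set r was 0.0090 at 0 h, 0.026 at 12 h, -0.22 at 36 h and -0.17 at 48 h, at percentiles 0.20, 0.30, 1.80 and 14.6. Cells of 1 sample are not replicates, so no p-value was computed for these 8 relations. With no cell left out, r turned to 0.34 at 24 h, 0.46 at 30 h, 0.22 at 36 h and 0.22 at 48 h.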

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

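The alternatives with cells of at least 1000 genes, detection among the 1000 highest genes, means without the highest cell of each gene, the GC trend removed and the comparisons of genes and list medians at 30 h against 6 h, 12 h or 36 h against 0 h and 48 h against 36 h were chosen after the data were seen, as were the mean list changes against 6 h, the counts of members past 50% of their change within a set and the 6 h ranges of the scores. Over 17 alternatives 2607 values were recomputed, of which 1690 stayed close, 883 moved and 34 changed sign, 20 of the latter with no cell left out. The setting with no cell left out adds the 400 cells with fewer than 2000 genes, many of them with fewer than 1000. At 6 h 58 of the 96 cells had at least 1000 genes, at 30 h 59, at 0 h 42 and at 48 h 56. How far the cells with few genes set the values of that setting was not tested. A fold was counted as moved at 1.5-fold, r at 0.15, a share outside its 95% interval, and a sign change for folds of at least 2-fold and r of at least 0.15. The core pluripotency median at 48 h against 0 h kept its sign in 11 of 11 alternatives, between -5.68 and -3.003. The pan-neuronal median kept it in 10 of 11, between 0 and 6.38, and was 0 with the median over cells. Cells of at least 4000 genes were absent at 36 and 48 h, so that filter gave no value there. Pooled counts and thinning to a fixed number of reads were not run, since TPM keeps no counts. No paired analysis was possible because cell numbers only name cells and no test was made. The 14 cells kept at 48 h, with a median of 2141 genes, limit every value at that time. The values that moved, and the folds that changed sign, follow by alternative, and the cause was not tested.

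With the GC trend removed, the median list log2 fold changes at 48 h against 0 h were -4.09 (core pluripotency), -0.65 (formative), 4.18 (neural progenitor), 5.86 (pan-neuronal), -1.99 (switch repressors), 6.504 (trophoblast and epithelium), -0.14 (S phase), 0.699 (G2 and M phase), -0.105 (cell cycle inhibitors), -2.202 (p53 targets), 1.43 (glycolysis), 0.59 (housekeeping). For the median list log2 fold changes at 48 h against 36 h the values were 0.94 (pan-neuronal). The mean log2 fold changes over all members of the core pluripotency list were -3.36 (48 h against 0 h). For the mean log2 fold changes over all members of the pan-neuronal list the values were 5.24 (48 h against 0 h).

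With no cell left out, the median list log2 fold changes at 12 h against 0 h were 2.08 (pan-neuronal). There, the median list log2 fold changes at 30 h against 6 h were -1.06 (formative), -0.39 (proneural cascade), 0.86 (pan-neuronal), 0.52 (axon guidance). Median list log2 fold changes at 36 h against 0 h were -1.898 (core pluripotency), 3.22 (pan-neuronal). The median list log2 fold changes at 48 h against 0 h were -1.96 (formative), 3.57 (pan-neuronal), -0.84 (G2 and M phase), 1.34 (cell cycle inhibitors), -0.71 (housekeeping). For the median list log2 fold changes at 48 h against 36 h the values were -0.48 (core pluripotency). Values of mean log2 fold changes over all members of the core pluripotency list were -2.41 (36 h against 0 h), -2.77 (48 h against 0 h), 0.010 (18 h against 6 h), -0.101 (24 h against 6 h). There, the mean log2 fold changes over all members of the pan-neuronal list were 1.24 (12 h against 0 h), 2.88 (36 h against 0 h), 3.08 (48 h against 0 h), 0.78 (30 h against 6 h). The reversed log2 fold changes at 30 h against 6 h were 2.097 (Cyp2e1), -0.031 (Ebf2), -1.51 (Elavl3), -0.66 (Fabp7), -0.042 (Lmo4), -0.057 (Nefm), -0.76 (Ptbp2), -1.51 (Slc18a3), -0.12 (T). For the reversed log2 fold changes at 48 h against 0 h the values were 0.85 (Actl6a), -0.58 (Aurkb), 1.77 (Gins2), 0.25 (Pou5f1), 1.01 (Ptbp1), -1.17 (Sox9), 0.68 (Trp53inp1). The steps per 6 h were 1.07 (24 to 30 h), 0.45 (36 to 48 h). The share with G2 and M genes, in percent, was 52.1 (0 h), 67.7 (6 h), 52.1 (12 h), 82.3 (18 h), 71.9 (24 h), 61.5 (30 h), 41.7 (36 h), 34.4 (48 h). Cells with Isl1 made up, in percent, 39.6 (6 h), 20.8 (12 h), 43.8 (18 h), 38.5 (24 h), 38.5 (30 h), 30.2 (36 h). For Lhx3 the percentages of cells were 41.7 (6 h), 30.2 (12 h), 45.8 (18 h), 44.8 (24 h), 42.7 (30 h), 17.7 (36 h). Detection of Pou5f1 and Mnx1, in percent of cells, was 27.1 (6 h), 23.96 (18 h), 18.8 (24 h). Pou5f1 and Tubb3 was found in these percentages of cells: 45.8 (6 h), 44.8 (18 h), 34.4 (24 h), 17.7 (30 h). The percentages of cells inside score ranges were 100 (48 h pluripotency), 100 (30 h pluripotency). The r of the scores were 0.686 (0 h), 0.665 (6 h), 0.748 (12 h), 0.452 (18 h), 0.337 (24 h), 0.4598 (30 h), 0.225 (36 h), 0.219 (48 h). The counts of members at 50% of their change were 3 (core pluripotency at 18 h), 7 (pan-neuronal at 18 h).

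With 5 G2 and M genes required, the percentages of cells with G2 and M genes were 76.9 (12 h), 50 (36 h), 42.9 (48 h).

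With cells of at least 1000 genes kept, the median list log2 fold changes at 48 h against 0 h were -3.83 (core pluripotency), 2.19 (proneural cascade), 4.02 (pan-neuronal), 3.85 (axon guidance), -0.27 (S phase), -1.52 (p53 targets). There, the median list log2 fold changes at 48 h against 36 h were -0.503 (core pluripotency). Mean log2 fold changes over all members of the core pluripotency list were -3.06 (48 h against 0 h). Values of reversed log2 fold changes at 30 h against 6 h were -0.77 (Slc18a3). There, the reversed log2 fold changes at 48 h against 0 h were 1.57 (Actl6a), 0.48 (Gins2), 0.055 (Ptbp1), 0.65 (Trp53inp1), 0.23 (Tyms). For the steps per 6 h the values were 0.51 (36 to 48 h). Cells with Isl1 made up, in percent, 58.3 (18 h). For Lhx3 the percentages of cells were 61.1 (18 h). Detection of Pou5f1 and Tubb3, in percent of cells, was 59.7 (18 h). For the percentages of cells inside score ranges the values were 64.3 (48 h pluripotency). For the r of the scores the values were 0.356 (0 h), 0.2303 (6 h), 0.1898 (18 h), -0.359 (24 h). For the counts of members at 50% of their change the values were 1 (core pluripotency at 24 h).

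With cells of at least 4000 genes kept, the percentages of cells with G2 and M genes were 100 (12 h), 100 (18 h), 100 (30 h). Values of percentages of cells inside score ranges were 54.7 (30 h pluripotency). Values of r of the scores were -0.353 (6 h), -0.226 (12 h), -0.497 (18 h).

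With detection among the 1000 highest genes, the percentages of cells with G2 and M genes were 62.2 (0 h), 75.5 (6 h), 46.2 (12 h), 62.5 (18 h), 50.9 (24 h), 45.6 (30 h), 34.1 (36 h). Cells with Isl1 made up, in percent, 7.69 (12 h), 3.57 (18 h), 7.02 (30 h), 22.7 (36 h), 0 (0 h, 6 h, 24 h). For Lhx3 the percentages of cells were 30.8 (12 h), 5.36 (18 h), 0 (0 h, 6 h, 24 h, 30 h). Detection of Neurog2, in percent of cells, was 0 (6 h, 12 h, 18 h, 24 h, 30 h, 36 h). Pou5f1 and Mnx1 was found in these percentages of cells: 0 (6 h, 18 h, 24 h, 30 h). The share with Pou5f1 and Tubb3, in percent, was 18.9 (6 h), 3.64 (24 h), 1.75 (30 h), 0 (0 h, 12 h, 18 h, 48 h).

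With detection at 10 TPM, the percentages of cells with G2 and M genes were 76.9 (12 h). For Isl1 the percentages of cells were 37.7 (6 h), 28.6 (18 h), 38.2 (24 h). Detection of Lhx3, in percent of cells, was 35.8 (6 h), 55.4 (18 h), 58.2 (24 h), 0 (0 h). Neurog2 was found in these percentages of cells: 1.89 (6 h), 7.14 (18 h), 5.26 (30 h), 0 (24 h). The share with Pou5f1 and Mnx1, in percent, was 15.1 (6 h), 14.3 (18 h). Cells with Pou5f1 and Tubb3 made up, in percent, 1.92 (12 h), 58.9 (18 h).

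With even-numbered cells alone, the median list log2 fold changes at 30 h against 6 h were 0.12 (proneural cascade), 1.85 (motor neuron), 1.54 (cell cycle inhibitors). The median list log2 fold changes at 36 h against 0 h were 3.495 (pan-neuronal). For the median list log2 fold changes at 48 h against 0 h the values were -5.53 (core pluripotency), -4.07 (formative), 3.37 (proneural cascade), 6.38 (pan-neuronal), 2.702 (axon guidance), 2.44 (trophoblast and epithelium), -4.02 (S phase), -2.88 (G2 and M phase), -1.48 (cell cycle inhibitors), -4.34 (p53 targets), -1.06 (glycolysis), -0.81 (housekeeping). Values of median list log2 fold changes at 48 h against 36 h were 1.85 (pan-neuronal). The mean log2 fold changes over all members of the core pluripotency list were -5.17 (48 h against 0 h). Reversed log2 fold changes at 48 h against 0 h were -3.12 (Isl1), -3.32 (Mki67). Values of steps per 6 h were 1.597 (36 to 48 h). For G2 and M genes the percentages of cells were 100 (30 h), 40 (48 h). Detection of Isl1, in percent of cells, was 85.7 (18 h), 0 (48 h). Lhx3 was found in these percentages of cells: 0 (0 h). There, the percentages of cells inside score ranges were 20 (48 h neuronal), 51.7 (30 h pluripotency). There, the r of the scores were -0.312 (6 h), 0.372 (12 h), 0.105 (18 h). Values of counts of members at 50% of their change were 3 (core pluripotency at 18 h), 2 (pan-neuronal at 18 h).

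With means rescaled to a median log2 ratio of 0, the median list log2 fold changes at 48 h against 0 h were -4.14 (core pluripotency), -2.02 (formative), 3.86 (neural progenitor), 1.44 (proneural cascade), 6.42 (Ebf and Onecut), 5.29 (pan-neuronal), 2.67 (axon guidance), -2.76 (switch repressors), 4.13 (trophoblast and epithelium), -0.41 (S phase), 0.71 (G2 and M phase), -0.102 (cell cycle inhibitors), -2.67 (p53 targets), 0.74 (glycolysis), 0.61 (housekeeping). For the mean log2 fold changes over all members of the core pluripotency list the values were -3.72 (48 h against 0 h). Values of mean log2 fold changes over all members of the pan-neuronal list were 4.79 (48 h against 0 h).

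With the median over cells, the median list log2 fold changes at 12 h against 0 h were -2.04 (core pluripotency), 0 (pan-neuronal). The median list log2 fold changes at 30 h against 6 h were -2.65 (core pluripotency), -0.33 (formative), 4.26 (neural progenitor), -0.087 (proneural cascade), 2.66 (axon guidance), -1.27 (epithelial adhesion), -0.84 (G2 and M phase), -1.34 (p53 targets), 2.88 (immediate early), 0 (motor neuron, pan-neuronal). For the median list log2 fold changes at 36 h against 0 h the values were -5.82 (core pluripotency), 0 (pan-neuronal). Values of median list log2 fold changes at 48 h against 0 h were -5.68 (core pluripotency), -3.43 (formative), -1.16 (switch repressors), -3.298 (S phase), -1.66 (G2 and M phase), -0.86 (p53 targets), -2.57 (glycolysis), -1.19 (housekeeping), 0 (neural progenitor, proneural cascade, Ebf and Onecut, pan-neuronal, axon guidance, trophoblast and epithelium). There, the median list log2 fold changes at 48 h against 36 h were 0 (core pluripotency). There, the mean log2 fold changes over all members of the core pluripotency list were -5.02 (36 h against 0 h), -5.16 (48 h against 0 h), -1.72 (24 h against 6 h), -2.203 (30 h against 6 h). Mean log2 fold changes over all members of the pan-neuronal list were 0.403 (12 h against 0 h), 0.17 (36 h against 0 h), 0.84 (48 h against 0 h), 0.65 (30 h against 6 h). The reversed log2 fold changes at 48 h against 0 h were 0.39 (Actl6a), -3.16 (Asns), -0.21 (Col1a2), -0.55 (Mki67), -0.598 (Ptbp2). There, the counts of members at 50% of their change were 2 (core pluripotency at 24 h), 7 (pan-neuronal at 18 h), 2 (pan-neuronal at 24 h).

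With no filter on low values, the median list log2 fold changes at 30 h against 6 h were 0.11 (formative), 0.21 (proneural cascade), 0.74 (axon guidance), 0.57 (immediate early). The median list log2 fold changes at 48 h against 0 h were -1.92 (formative), 2.41 (neural progenitor), 4.504 (Ebf and Onecut), -2.48 (switch repressors), 1.53 (trophoblast and epithelium), 0.796 (cell cycle inhibitors), -2.29 (p53 targets).

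With odd-numbered cells alone, the median list log2 fold changes at 30 h against 6 h were -1.28 (epithelial adhesion), 1.22 (cell cycle inhibitors). Values of median list log2 fold changes at 48 h against 0 h were -1.96 (formative), -3.65 (proneural cascade), 3.18 (pan-neuronal), -0.24 (S phase), 1.02 (G2 and M phase), -4.72 (p53 targets), -0.69 (glycolysis). There, the median list log2 fold changes at 48 h against 36 h were -0.99 (pan-neuronal). The mean log2 fold changes over all members of the pan-neuronal list were 3.02 (48 h against 0 h). For the reversed log2 fold changes at 48 h against 0 h the values were -0.44 (Asns). The share with G2 and M genes, in percent, was 100 (18 h), 100 (24 h), 100 (48 h). Cells with Isl1 made up, in percent, 0 (0 h). For Pou5f1 and Tubb3 the percentages of cells were 71.4 (24 h), 0 (48 h). Percentages of cells inside score ranges were 100 (30 h pluripotency), 64.3 (30 h neuronal). R of the scores were 0.279 (6 h), -0.134 (12 h), -0.224 (18 h), -0.179 (30 h). Counts of members at 50% of their change were 1 (core pluripotency at 24 h), 9 (pan-neuronal at 18 h).

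With a pseudocount of 0.1, the median list log2 fold changes at 48 h against 0 h were -5.61 (core pluripotency), 3.95 (neural progenitor). For the mean log2 fold changes over all members of the core pluripotency list the values were -5.46 (48 h against 0 h). Values of mean log2 fold changes over all members of the pan-neuronal list were 4.85 (48 h against 0 h).

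With a pseudocount of 10, the median list log2 fold changes at 30 h against 6 h were 0.53 (motor neuron), 1.00 (axon guidance). For the median list log2 fold changes at 36 h against 0 h the values were 3.34 (pan-neuronal). Values of median list log2 fold changes at 48 h against 0 h were -3.003 (core pluripotency), 2.09 (neural progenitor), 4.64 (Ebf and Onecut), 3.83 (pan-neuronal), 1.45 (axon guidance), -2.23 (switch repressors), 2.30 (trophoblast and epithelium), -1.91 (p53 targets). There, the mean log2 fold changes over all members of the core pluripotency list were -2.42 (36 h against 0 h), -2.898 (48 h against 0 h). Mean log2 fold changes over all members of the pan-neuronal list were 1.09 (12 h against 0 h), 2.54 (36 h against 0 h), 2.96 (48 h against 0 h). The counts of members at 50% of their change were 2 (core pluripotency at 24 h).

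With ranges from the 5th to the 95th percentile, the percentages of cells inside score ranges were 50.9 (30 h pluripotency), 70.2 (30 h neuronal).

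With scores without the 3 highest genes, the r of the scores were 0.25 (12 h).

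With means taken without the highest cell of each gene, the median list log2 fold changes at 48 h against 0 h were -5.57 (core pluripotency), -3.697 (formative), -1.68 (proneural cascade), 5.02 (Ebf and Onecut), -0.67 (G2 and M phase), -1.61 (cell cycle inhibitors), -4.42 (p53 targets), -1.08 (glycolysis). Median list log2 fold changes at 48 h against 36 h were -2.49 (core pluripotency). The mean log2 fold changes over all members of the core pluripotency list were -5.41 (48 h against 0 h). For the mean log2 fold changes over all members of the pan-neuronal list the values were 3.17 (48 h against 0 h).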

Other observations

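The tests of time after induction, of length and GC trends removed together, of genes detected per cell, of library sets and of mesoderm markers were chosen after the result was seen, as were the genes of this part outside the fixed lists. T (Brachyury), a mesoderm factor, was above 0 in 7.55% of cells at 6 h, 39.3% at 18 h, 32.7% at 24 h and 31.6% at 30 h. At 12 h against 0 h the highest genes by log2 fold change were Lhx3 (6.98), Slc18a3 (6.36), Tagln3, a neuronal calponin family gene (5.54), Krt8 (5.47) and Ebf2 (5.29), and Fgf4 (-5.30) was the lowest. Of the cells left out for few genes, Lhx3 was above 0 in 1 of 59 at 0 h and 6 of 82 at 48 h (7.32%, 2.73 to 15.2%).

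By Sod1 and Gapdh the 8 time points split into 2 library sets, 0, 12, 36 and 48 h against 6, 18, 24 and 30 h, although 36 and 48 h correlated with 0 and 12 h and with each other at a Spearman rho of 0.482 to 0.646, inside the range of pairs across the sets (0.410 to 0.654). Time after induction would place 12 h between 6 h and 18 h, but the distances of 12 h to them were at least 2.19 times the distance between 6 h and 18 h. The first tests of transcript length and GC content left both open, with a Spearman rho over genes of 0.188 and 0.132 for the ratio of 12 h to 18 h, against -0.0482 and 0.394 for 24 h to 18 h, and a further test was added for that reason. With both trends removed the distance of 12 h to 18 h was still 2.45 times that of 18 h to 24 h (2.15 and 2.40 in odd-numbered and even-numbered cells). Without the 100 most abundant genes it was 2.13 times (1.86 and 2.11). The means at 12 h were noisier, however. Odd-numbered and even-numbered cells differed by 1.73 at 12 h, against 0.78 at 18 h and 0.74 at 24 h. That noise raises each distance to 12 h by an amount that was not estimated. How far the ratios argue against either as the whole cause was therefore not settled. The 2 library batches that the labels state may be these sets, which was not tested because the cells of each batch are not given in the sources used here.

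Pluripotency genes were lower and neuronal genes higher at 48 h than at 0 h. Fewer genes detected per cell would also lower matched random lists, and the core pluripotency median lay at percentile 0 of them (0 and 0.05 in odd-numbered and even-numbered cells). These lists were matched on the mean over all kept cells and not on the 0 h level, and they also drew on genes higher at 48 h. They therefore cannot exclude the fewer genes per cell as a source. A difference between library sets stays open, since 48 h was placed with 0 h by Sod1 and Gapdh and not by correlation. Between time points that did correlate, the lists moved apart in both sets, with pan-neuronal and core medians of 1.46 and -0.99 at 12 h against 0 h and a gap of 2.82 (3.14 and 2.58) at 30 h against 6 h, which does not test the libraries at 48 h. The size of the change at 48 h stays open too, since the depth and the 14 cells bear on it, and a response to the induced factors is untested as its source, since no uninduced cells at the later times were analysed here.

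T was detected in more cells at 18, 24 and 30 h than at 6 h, and the median number of genes per cell differed by -1003 between 30 h and 6 h (-852.5 and -1137 in odd-numbered and even-numbered cells), so deeper cells do not account for it. Mesoderm differentiation stays open: 0 of 5 other mesoderm markers were found in more cells at 30 h than the interval at 6 h allows, but 0 of the 5 passed the filter, and Tbx6 had 0.228 TPM at 6 h and 1.76 at 30 h. Cells that leave the neuronal programme are a candidate source: over the 57 cells at 30 h T and the neuronal score had a Spearman rho of -0.407, at percentile 0.336 of 3571 genes of like detection, and -0.497 without the 2 farthest cells. Cells still pluripotent stay open as well, with a rho of T and the pluripotency score of 0.376, 0.438 and 0.166 at 18, 24 and 30 h. The rho with the neuronal score was -0.265 at 24 h and -0.0708 at 18 h, so the relation was not seen at each time, and the fold of T turned to -0.12 with no cell left out.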
